A study of Mus musculus with 9 samples.

How the data were processed

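The series measured gene expression in bone marrow stromal cells of Cxcl12-GFP mice on Affymetrix Mouse Gene 1.0 ST arrays, 9 in all, with 4 arrays of mice given phosphate-buffered saline (PBS) and 5 of mice given granulocyte colony-stimulating factor (G-CSF). Per the labels' protocols, sorted cells went directly into TRIzol LS, and RNA was amplified with a NuGEN Pico SL Ovation kit and labelled with biotin by a NuGEN Encore kit. Amplification of small RNA amounts and hybridisation both add spread between arrays that the deposited values cannot separate from biological spread. Groups and replicate numbers were taken from the sample titles. The titles call the arrays biological replicates, but the animals or pools behind them are not identified, so p-values measure the spread between these arrays.

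The deposited intensity values were made by the authors with RMA (background correction, normalisation between arrays and summary per probe set) in Affymetrix Expression Console, per the submitters' processing notes. The versions and library files were not given in the sources used here. The deposited intensity values ranged from 1.73 to 15673.1 with array medians of 34.72 to 37.24, which shows a linear scale. The design had assumed log2 values, so log2 was taken here before any test, as the design allowed for. RMA normalises arrays to a shared distribution before the summary per probe set. A change in total RNA per cell therefore cannot be seen, and differences are relative to the other transcripts. The summarised log2 values still differed in spread, with interquartile ranges of 2.45 (PBS replicate 3) to 2.99. RMA values carry no detection call, so low values were not called absent. The number of arrays limits the precision.

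Of the 35553 probe sets, the platform table paired 21789 with 1 gene symbol, 1621 with several and listed no symbol for 12143. Those with 1 symbol were tested, and no gene was named from a probe set with several. The table's gene identifiers matched 21698 of them in a mouse gene table of assembly GRCm38.p6, used for names only, and left 91 unmatched. No symbol needed an update. The tested probe sets covered 19938 genes, 999 of them by several probe sets. For such genes, lists and named genes used the probe set with the highest mean over all arrays. Of 12 changed genes with several probe sets, 8 had probe sets that differed in call and 5 had probe sets of opposite sign. No coordinates were used because the sources used here name no genome build for the probe sets.

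The comparison of G-CSF with PBS used limma 3.58.1 (lmFit and eBayes with default settings) in R 4.3.3 on all 9 arrays, without covariates, two-sided. A probe set counted as changed at a Benjamini-Hochberg adjusted p under 0.05. Gene lists were tested with limma's camera at a preset correlation between genes of 0.01, with adjustment over 31 lists (19 pathway lists and 12 cell-type lists). Camera was run again with the correlation estimated from the data. Members of each list were counted as risen, fallen or not past the threshold, both over all genes tested and adjusted over the list alone. The Hspa9 level was compared by an exact permutation test, two-sided. The groups, tests, lists and naming rule were fixed before the data were examined.

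The rule for named genes took the 12 largest rises and 12 largest falls among changed genes whose G-CSF arrays all lay on one side of the PBS arrays, without predicted or clone names. It added 13 key genes whatever their result, the 4 members with the smallest p of each list that passed, and the 2 with the smallest p of every other list. Other genes are marked in the text as chosen after their values were seen.

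Alternatives fixed beforehand were all probe sets, brighter probe sets only, eBayes with trend and robust settings, a further quantile normalisation, median centring, array weights, a mean over a gene's probe sets, the replicate number as a block, other thresholds, camera with an estimated correlation or with a variance trend, fry, and each array left out in turn. Alternatives chosen after seeing the data were the array set as a block, each array set alone, G-CSF replicates 4 and 5 averaged as 1 replicate, and the neutrophil list mean as a covariate. The 2 array sets are a split seen in the values that the labels do not name.

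The steps were tested on simulated data drawn from the means and spreads of the 21789 probe sets. Of 50 probe sets changed by each log2 size, 14% were recovered at 0.5, 64% at 1, 92% at 1.5 and 100% at 2. There were 6 false calls among 21589 unchanged probe sets, and 0 calls when nothing was changed. A shifted gene list was called at the preset correlation, and so was 1 of 28 lists that shared no gene with it. The simulated genes varied independently and held no array sets, whereas the estimated correlation in the data reached 0.54 (immediate early genes). The simulation therefore does not show how often correlated lists are called falsely.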

Results

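CXCL12-abundant reticular (CAR) cells are bone marrow stromal cells that produce the chemokine Cxcl12 and other factors used by blood stem cells and developing B cells. The series examined how granulocyte colony-stimulating factor (G-CSF), a cytokine that raises neutrophil output and mobilises stem cells, changes these cells. Mice carried a green fluorescent protein in the Cxcl12 locus, and lineage-negative cells bright for that protein had been sorted from their marrow. RNA was profiled on 5 arrays of mice given G-CSF at 250 µg/kg per day for 5 days and on 4 arrays of mice given saline (PBS). Levels are log2 RMA intensities, given as mean ± SD over arrays, and changes are G-CSF minus PBS on the log2 scale with the standard error (SE) of the limma fit.

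The GEO source names of these samples name pre-B colonies, and 4 name an Hspa9 genotype, which the titles, treatments and protocols contradict. Groups therefore follow the titles. Hspa9 did not separate the groups, at 7.42 ± 0.34 in PBS (n = 4) and 7.54 ± 0.30 in G-CSF (n = 5; difference 0.12, exact permutation p = 0.563, where the smallest possible p is 0.00794). The sign of this difference depended on 1 array, since it was -0.03 without PBS replicate 3. The test compared the treatment groups and did not use which 4 arrays carry the genotype name. It therefore does not settle the source names.

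The first principal component, with 34.9% of the variance, split the arrays into 2 sets that each held both groups. Set 1 was PBS replicates 1 and 2 with G-CSF replicates 1 to 3, and set 2 was the remaining 4 arrays. Ribosomal protein transcripts averaged 10.08 ± 0.12 in set 1 (n = 5) and 9.29 ± 0.36 in set 2 (n = 4). Within set 2, PBS replicate 3 stood apart from the other arrays. It lay at 56.5 on the first component, against 22.5 for the next array (PBS replicate 4), and its ribosomal mean was 8.78. Its interquartile range of 2.45 was the narrowest, with 2.71 the next. Treatment separated the arrays on the second component (20.0% of the variance). The labels name no batch, so values with the set as a block and within each set are given beside the main results.

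After G-CSF, lists of B cell and stem cell support, stromal identity and adipocyte genes shifted downward in the sorted cells. Lists of matrix genes, of acute phase genes and of smooth muscle and pericyte markers shifted upward. Bmp4, Chrdl1, Il15 and Il7 were among the 12 largest falls by the naming rule, which were led by Car1 and Adh1. Timp1, Ifitm1 and Aebp1 were among the 12 largest rises, which were led by Wfdc17. Of 21789 probe sets, 353 changed at adjusted p under 0.05 in limma, for 344 genes. Expression rose for 162 probe sets and fell for 191, of which 108 and 102 changed at least 2-fold. The G-CSF arrays all lay on one side of the PBS arrays for 347 of the 353, and for 1013 of all probe sets (4.65%, against 1.59% by chance). The 353 all had the same sign in both array sets, which selection over both sets favours, while over all probe sets the changes of the sets correlated at 0.39 across genes, which are not independent replicates. All 353 passed with the set as a block, when 598 probe sets were called; within sets, 202 were called in set 1 and 59 in set 2. The mean of neutrophil marker genes was 7.57 ± 0.63 in PBS and 8.49 ± 0.28 in G-CSF, and with this mean as a covariate 49 probe sets were called. The count fell to 210 without PBS replicate 1, 222 without G-CSF replicate 1 and 224 without G-CSF replicate 4.

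**Figure D1:**
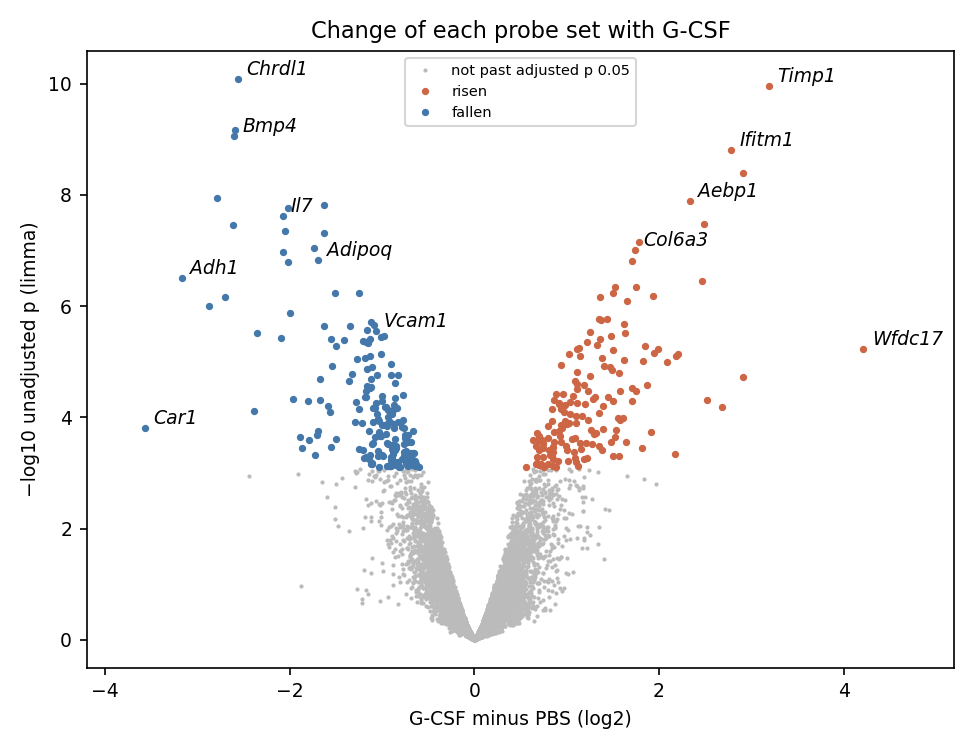
Each point is a probe set with 1 gene symbol, with the change on the log2 scale (G-CSF minus PBS) on the x axis and -log10 of limma's unadjusted p on the y axis. Red points are the 162 that rose and blue points the 191 that fell at adjusted p under 0.05; changes ran from -3.57 (Car1) to 4.21 (Wfdc17).

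The largest rise was that of Wfdc17, a small secreted protein with a WAP domain, from 5.32 ± 1.15 to 9.53 ± 1.02 (change 4.21, SE 0.56, adjusted p = 0.00193). Timp1, an inhibitor of matrix metalloproteinases, rose 9.11-fold, from 7.18 ± 0.18 to 10.37 ± 0.24 (adjusted p = 1.22e-06). Ifitm1, an interferon-inducible membrane protein, rose by 2.78, and its other probe set by 2.91. Stfa3 (2.91) and Stfa2 (2.52), cysteine protease inhibitors abundant in granulocytes, and Saa3 (2.68), an acute phase protein, also rose. The remaining genes among the 12 largest rises were Pamr1 (2.49), Ugcg (2.47), Aebp1 (2.33), Rgs16 (2.21), Lipg (2.19) and Serpinb1a (2.09). Stfa2 and Stfa3 belong to a family of near-identical genes, and cross-hybridisation leaves the responding member uncertain. Saa3 and Ifitm1 also have related genes, and cross-hybridisation was not tested for them. The largest fall was that of Car1, carbonic anhydrase 1 of red cell precursors, from 7.37 ± 1.95 to 3.80 ± 0.24 (change -3.57, adjusted p = 0.0176). Adh1, an alcohol dehydrogenase, fell 9.02-fold, and Slc26a7, an anion exchanger, fell 6.92-fold. Rspo2, an enhancer of Wnt signalling, fell by 2.70, and Ogn (osteoglycin), a small proteoglycan, fell by 2.62. Bmp4, a bone morphogenetic protein, fell 6.06-fold, from 9.59 ± 0.21 to 6.99 ± 0.20 (adjusted p = 4.84e-06). Chrdl1, a secreted antagonist of bone morphogenetic proteins, fell 5.92-fold (adjusted p = 1.22e-06). The remaining genes among the 12 largest falls were Cnnm1 (-2.59), Gpr50 (-2.39), Il15 (-2.36), Slco1a4 (-2.09) and Il7 (-2.08). Of the 60 named genes that passed the threshold, 40 kept their calls whichever array was left out, and 20 lost them for at least 1 array. Car1 was among the 20, with an adjusted p of 0.0617 without PBS replicate 1, and was also lost without PBS replicate 4 or G-CSF replicate 1.

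The list of genes for B lymphopoiesis support shifted downward after G-CSF, with members in both directions. Of 14 measured, 6 fell, 0 rose and 8 did not pass; adjusted over the list alone, 9 fell and 3 rose (Il6, Lgals1 and Tnfsf11, the last 2 at 1.00 and 0.68 and chosen after their values were seen). Il7, the cytokine required by B cell progenitors, fell 4.22-fold, to 5.92 ± 0.23 in G-CSF (change -2.08, SE 0.17, adjusted p = 4.78e-05). Il15, a cytokine for lymphocytes and natural killer cells, fell 5.13-fold (adjusted p = 0.00141). Igf1, a growth factor for pro-B cells, fell 2.22-fold (adjusted p = 0.00166), and Vcam1, the adhesion partner of the integrin VLA-4, fell 2.10-fold (adjusted p = 0.00134). Kitl (stem cell factor) fell 1.67-fold, from 10.82 ± 0.22 to 10.08 ± 0.09 (adjusted p = 0.0231). Bmp6, a bone morphogenetic protein, was the remaining gene that fell over all genes (-0.97, chosen after its values were seen). Cxcl12, on which the sort depends, was at 12.35 ± 0.11 in PBS and 11.99 ± 0.07 in G-CSF. It did not pass over all genes (change -0.36, adjusted p = 0.287), although its G-CSF arrays all lay below its PBS arrays. Il6 (1.17, adjusted p = 0.371, and 0.0404 without G-CSF replicate 3), Flt3l (-0.41, adjusted p = 0.494) and Tnfsf13b, also called BAFF (0.09, adjusted p = 0.967), did not pass over all genes. Adjusted over the list alone, Cxcl12 and Flt3l were among the 9 that fell. With 1 array left out, Flt3l was at -0.26 (without PBS replicate 1) to -0.53 and Tnfsf13b at 0.04 (without PBS replicate 1) to 0.19 (without PBS replicate 4), again without a call. The list had a median change of -0.57 and passed camera at adjusted p = 6.50e-08 (0.0136 with an estimated correlation and 2.42e-07 with the set block). The list median was -0.76 in set 1 and -0.46 in set 2. Within sets 1 and 2, Il7 fell by 2.30 and 1.84, Igf1 by 0.97 and 1.31, and Kitl by 0.89 and 0.61. The Kitl call was lost without any 1 of PBS replicates 1 and 2 and G-CSF replicates 1, 2, 4 and 5, at adjusted p of up to 0.0793 without PBS replicate 2.

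The list of hematopoietic stem cell niche factors also shifted downward. Of 18 measured, 4 fell, 0 rose and 14 did not pass. Adjusted over the list alone, 7 fell, Cxcl12 among them, and 1 rose (Lif, at 0.79). Besides Vcam1 and Kitl, those that fell over all genes were Angpt1 and Csf1. Of these 4, 3 (Vcam1, Kitl and Angpt1) also belong to the stromal identity list described below. So do 3 of the 6 that fell in the B lymphopoiesis support list, so the falls of these lists are not independent. Angpt1, a ligand of the receptor Tie2, fell 2.38-fold (from 9.48 ± 0.07 to 8.22 ± 0.15, adjusted p = 4.38e-04). Csf1, the macrophage growth factor, fell 2.17-fold (adjusted p = 0.00109). The list passed camera at adjusted p = 3.53e-05 (0.0245 with an estimated correlation and 8.18e-05 with the set block), with a median of -0.28 (-0.13 without PBS replicate 3), -0.20 in set 1 and -0.34 in set 2. Of the ligands known to restrain lymphoid cells, 20 were measured, 1 rose and 1 fell, over all genes and adjusted over the list alone. Tnf rose by 0.84, from 4.72 ± 0.18 to 5.57 ± 0.32 (adjusted p = 0.0376), and the member that fell was Bmp4. That list did not pass camera (adjusted p = 0.109, and 0.261 with an estimated correlation). Within sets, it passed camera upward in set 2 (median 0.23, adjusted p = 0.0262) but not in set 1 (median 0.10, adjusted p = 0.358). The Tnf call was lost in 7 of 9 fits that left out 1 array, all but those without G-CSF replicate 4 or 5, at adjusted p of up to 0.116 without PBS replicate 1.

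**Figure D2:**
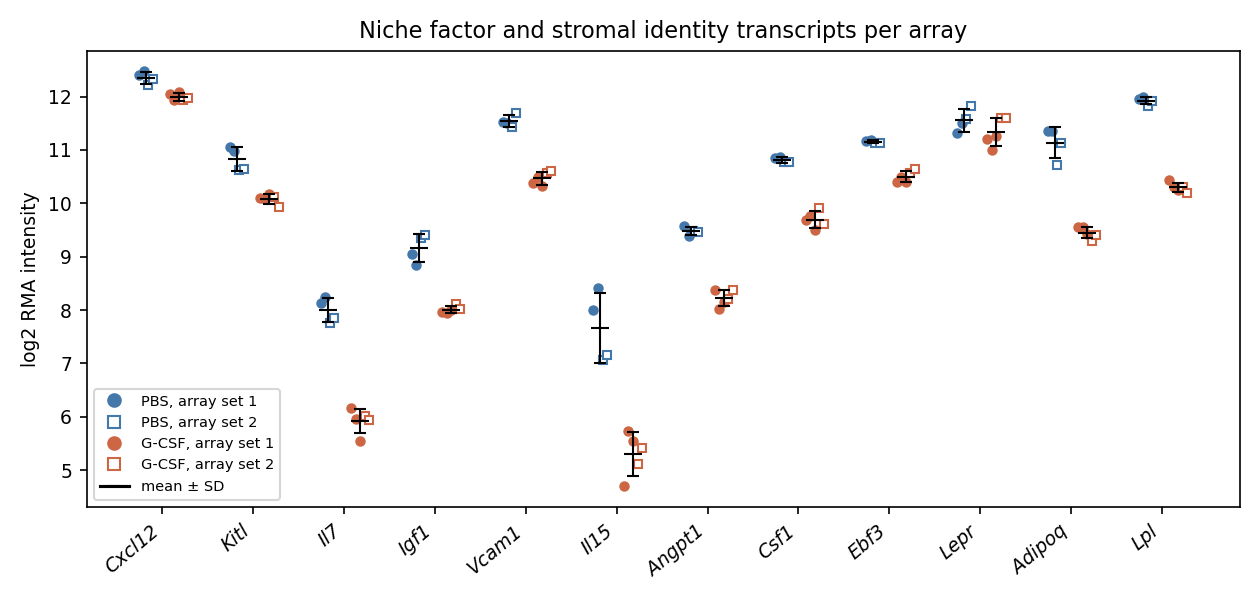
Log2 RMA intensity of 12 niche and identity genes on each array, for 4 PBS (blue) and 5 G-CSF (red) arrays, with filled circles for array set 1 and open squares for set 2; bars give mean ± SD. Vcam1 lay at 11.54 ± 0.11 in PBS and 10.47 ± 0.12 in G-CSF, whereas Lepr overlapped between the groups.

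The list of identity genes of CAR cells and leptin receptor positive stroma shifted downward. Of 33 measured, 12 fell, 1 rose and 20 did not pass; adjusted over the list alone, 16 fell and 1 rose. Besides Chrdl1, Il7, Vcam1, Angpt1 and Kitl, the genes that fell included Lpl, a lipoprotein lipase (3.09-fold, adjusted p = 3.73e-05), Gas6, a ligand of TAM receptors (3.09-fold, adjusted p = 7.08e-05), and Adipoq, adiponectin (3.23-fold). Ebf3, a transcription factor of these cells, fell 1.58-fold, from 11.16 ± 0.03 to 10.50 ± 0.11 (adjusted p = 0.0194). Foxc1, another such factor, did not pass (-0.88, adjusted p = 0.214) but passed with the set block at 0.00871. Lepr itself was at 11.55 ± 0.21 and 11.33 ± 0.26 and did not pass (adjusted p = 0.839). The member that rose was Il1rn, the interleukin-1 receptor antagonist (0.73; chosen after its values were seen). The list mean went from 10.63 ± 0.10 (n = 4) to 10.05 ± 0.02 (n = 5), and camera gave an adjusted p of 1.74e-17 (0.0136 with an estimated correlation and 2.86e-17 with the set block). The list median was -0.51 in set 1 and -0.32 in set 2. The Ebf3 call was lost without any 1 of PBS replicates 1, 2 and 4 and G-CSF replicates 1 and 3, at adjusted p of up to 0.0613 without PBS replicate 2.

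The list of adipocyte lineage genes shifted downward. Of 23 measured, 4 fell (7 adjusted over the list alone), 0 rose and 19 did not pass. They were Adipoq, Lpl, Pparg, the main adipogenic transcription factor (2.85-fold, from 9.01 ± 0.26 to 7.50 ± 0.17, adjusted p = 4.38e-04), and Cebpa (-0.77, adjusted p = 0.0143). Of these 4, Adipoq and Lpl also belong to the identity list. Camera gave an adjusted p of 1.84e-06 (0.0297 with an estimated correlation and 7.63e-07 with the set block), with a median of -0.19, -0.38 in set 1 and -0.10 in set 2. Without PBS replicates 2, 3 and 4 the median was -0.10, -0.33 and -0.30. The Cebpa call was lost without PBS replicate 1 (adjusted p = 0.0514). In the osteoblast lineage list, 2 of 20 genes rose (3 adjusted over the list alone) and 2 fell (7 adjusted over the list alone). Mmp13, a collagenase, rose 3.26-fold (adjusted p = 1.57e-04) and Col1a1, the main collagen of bone, rose 2.57-fold. Phex, a membrane protease of the osteoblast lineage, fell 4.19-fold (adjusted p = 1.22e-04), and Omd (osteomodulin) fell by 1.11 (chosen after its values were seen). That list did not pass camera (adjusted p = 0.218; adjusted p = 0.457 with an estimated correlation). Of 15 chondrocyte lineage genes, only Comp passed, over all genes and adjusted over the list alone, and it fell by 0.88 (adjusted p = 0.0357); Sox9 was at -0.44 (adjusted p = 0.327). Camera did not pass for that list (adjusted p = 0.938), nor for mature osteoblast and osteocyte markers, of which 1 of 7 rose (Col1a1) and 1 fell (Phex; 2 adjusted over the list alone; adjusted p = 0.355). The chondrocyte and the mature osteoblast lists differed in sign between the median change and the test. The Comp call was lost in 8 of the 9 fits that left out 1 array, all but that without PBS replicate 3, at adjusted p of up to 0.115 without PBS replicate 1.

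The list of extracellular matrix genes shifted upward. Of 41 measured, 11 rose, 3 fell and 27 did not pass; adjusted over the list alone, 15 rose and 3 fell. Besides Timp1, Col6a3, a collagen VI chain, rose 3.33-fold (from 6.06 ± 0.27 to 7.80 ± 0.14, adjusted p = 1.19e-04), Col12a1 rose 2.87-fold (adjusted p = 3.83e-04), and Timp3 rose 3.09-fold (adjusted p = 0.00141). Col1a1 rose within both sets, by 1.63 in set 1 and 1.00 in set 2, while Col1a2, the partner chain of collagen I, was at 0.10 (adjusted p = 0.973; chosen after its values were seen). The 3 that fell were Fbln5 (-0.69), Tnc (-0.66) and Nid2 (-0.64), also chosen after their values were seen. The list had a median change of 0.19, and camera gave an adjusted p of 1.29e-10 (0.0297 with an estimated correlation and 2.27e-10 with the set block). The median was 0.19 in set 1 and 0.26 in set 2. The list of smooth muscle and pericyte markers shifted upward as well, with 2 of 14 risen (5 adjusted over the list alone), 0 fallen and 12 not past the threshold. It is 1 of the cell-type lists fixed as markers of other cells that the sort could hold. Whether such cells were more frequent after G-CSF was not tested. Acta2, smooth muscle actin, rose 2.98-fold, from 5.04 ± 0.12 to 6.62 ± 0.56 (adjusted p = 0.00644), and Rgs4, a regulator of G protein signalling, rose 2.46-fold (adjusted p = 0.0213). Tagln was at 1.02 (adjusted p = 0.0691, and 0.0190 with the set block) and Rgs5 at 0.56 (adjusted p = 0.299). Camera gave an adjusted p of 1.33e-05 (0.0144 with an estimated correlation and 6.95e-06 with the set block), with a median of 0.34 in set 1 and 0.28 in set 2. The Rgs4 call was lost without any 1 of PBS replicates 1, 3 and 4 and G-CSF replicates 1 and 3, at adjusted p of up to 0.0624 without PBS replicate 4.

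**Figure D3:**
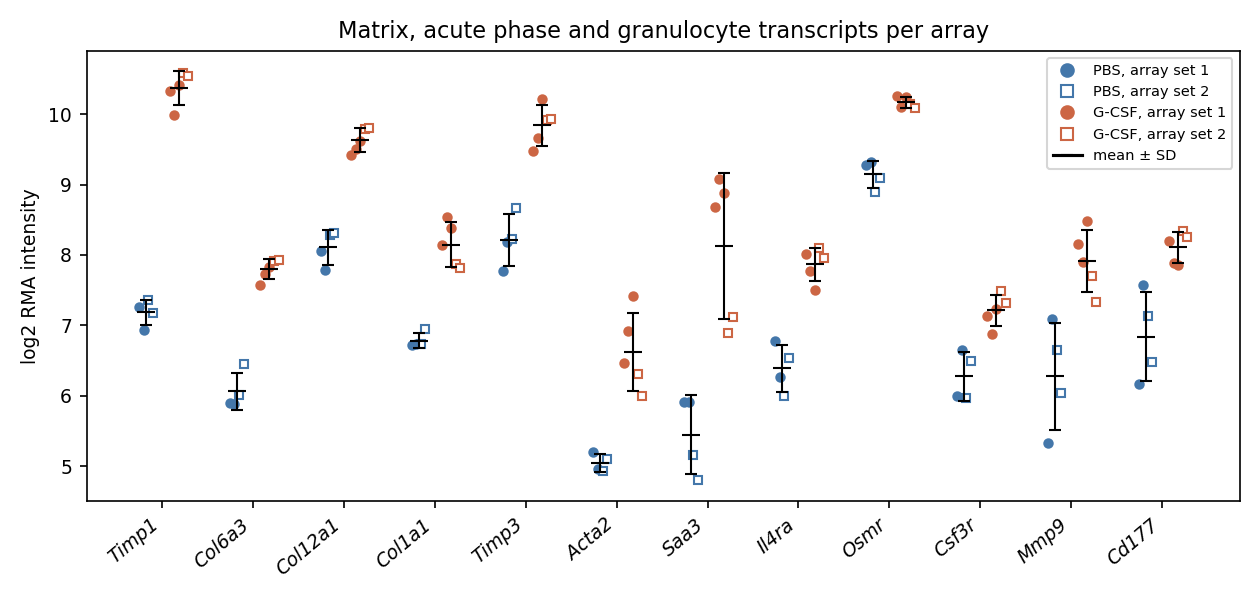
Log2 RMA intensity of 12 matrix, acute phase and granulocyte genes on each array, with the symbols as filled circles for array set 1 and open squares for set 2, blue for PBS (4 arrays) and red for G-CSF (5 arrays); bars give mean ± SD. Timp1 lay at 7.18 ± 0.18 in PBS and 10.37 ± 0.24 in G-CSF, and Saa3 was higher in set 1 than in set 2 in both groups.

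The list of STAT3 and acute phase genes shifted upward. Of 27 measured, 5 rose (7 adjusted over the list alone), 0 fell and 22 did not pass. Besides Timp1 and Saa3, Il4ra, the interleukin-4 receptor alpha chain, rose 2.79-fold (from 6.39 ± 0.34 to 7.87 ± 0.23, adjusted p = 0.00151). Osmr, the oncostatin M receptor, rose 2.03-fold (adjusted p = 0.00219), and Lrg1 rose by 1.48 (chosen after its values were seen). Camera gave an adjusted p of 5.73e-09 (0.0136 with an estimated correlation and 3.84e-08 with the set block), with a median of 0.33 in set 1 and 0.27 in set 2. Neutrophil markers were higher as well, by a median of 0.96. Inflammatory cytokines and NF-kB targets had 1 member risen (Tnf), 1 fallen (Csf1) and 28 of 30 not past the threshold; adjusted over the list alone, 3 rose and 1 fell. This list passed camera upward (adjusted p = 0.00130), but not with an estimated correlation (adjusted p = 0.261 with an estimated correlation). Within sets, its adjusted p was 0.111 in set 1 (median 0.35) and 8.66e-06 in set 2 (median 0.46), and the median of 0.42 became 0.24 without PBS replicate 3. Lif was at 0.79 (adjusted p = 0.109) and Nfkb2 at 0.57 (adjusted p = 0.171).

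The list of interferon response genes shifted downward. Of 29 measured, 3 fell (6 adjusted over the list alone), 0 rose and 26 did not pass. They were Ifit3, an interferon-induced antiviral protein (3.71-fold, adjusted p = 0.0227), Cxcl9, a chemokine induced by interferon gamma (3.23-fold, from 10.41 ± 0.52 to 8.72 ± 0.63, adjusted p = 0.0194), and Rtp4 (1.85-fold, adjusted p = 0.0312). Ifit1 was at -1.03 (adjusted p = 0.0682, and 0.0468 without PBS replicate 3); Ifit1 and Ifit3 have close relatives to which their probes could also bind. Camera gave an adjusted p of 2.83e-10 (0.0284 with an estimated correlation and 5.65e-10 with the set block), with a median of -0.38 in set 1 and -0.27 in set 2. Ifitm1, named above, rose although it is interferon-inducible, and is no member of the list. The antigen presentation list, of which 1 of 14 members fell (Cd74, the invariant chain, by 1.02, adjusted p = 0.0220) both over all genes and adjusted over the list alone, passed camera downward at adjusted p = 5.04e-04. That call was lost with an estimated correlation (adjusted p = 0.0657 with an estimated correlation) and in set 2 (median -0.10, adjusted p = 0.142; -0.41 in set 1). B cells and macrophages also express Cd74, and their markers are described below. With 1 array left out, the Ifit3 call was lost without PBS replicates 1, 3 or 4 or G-CSF replicates 1, 3 or 4, and the Cxcl9 call without PBS replicates 2 or 4 or G-CSF replicates 1 or 4. The Rtp4 call was kept only without PBS replicates 1 or 2, and the Cd74 call only without PBS replicate 3 or G-CSF replicate 5. Their highest adjusted p were 0.0725 (without PBS replicate 4), 0.0545 (without G-CSF replicate 1), 0.0821 (without G-CSF replicate 5) and 0.0707 (without PBS replicate 4).

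**Figure D4:**
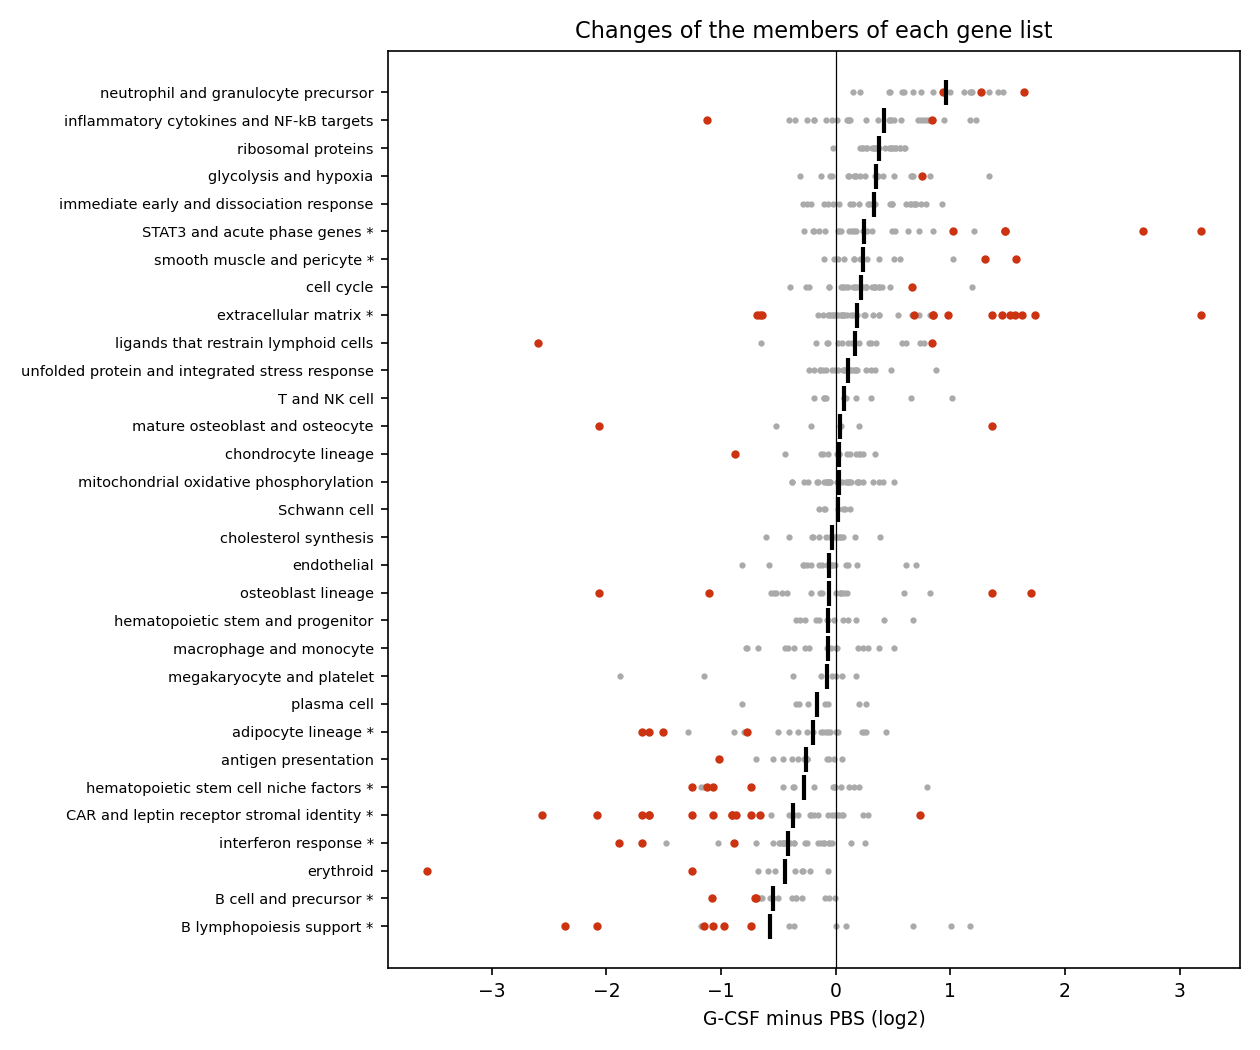
Changes of the measured members of the 31 gene lists on the log2 scale (G-CSF minus PBS, x axis), with 1 point per gene, red where the gene passed the threshold, and a black bar at the median. An asterisk marks the 9 lists at adjusted p under 0.05 with an estimated correlation; the median was -0.57 for B lymphopoiesis support and 0.19 for extracellular matrix.

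Markers of other marrow cells were measured because the sort could hold such cells. Neutrophil and granulocyte precursor genes were higher in G-CSF, with a median change of 0.96. Of 20 measured, 3 rose, 0 fell and 17 did not pass; adjusted over the list alone, 14 rose. Mmp9, a gelatinase of neutrophil granules, rose 3.12-fold (adjusted p = 0.0257), Cd177, a neutrophil surface protein, rose 2.41-fold (adjusted p = 0.0274), and Csf3r, the G-CSF receptor, rose 1.91-fold, from 6.28 ± 0.35 to 7.21 ± 0.23 (adjusted p = 0.0262). The mean of the list was 7.57 ± 0.63 in PBS (n = 4) and 8.49 ± 0.28 in G-CSF (n = 5), and the arrays overlapped, since PBS replicate 2 was at 8.45 and the lowest G-CSF array at 8.02. Camera gave an adjusted p of 7.13e-15 (1.03e-12 with the set block; median 0.75 in set 1 and 1.14 in set 2), lost with an estimated correlation (adjusted p = 0.0657 with an estimated correlation). With the list mean as a covariate, the 9 lists that passed with an estimated correlation still passed camera with the preset correlation, whereas 24 of the 60 named genes kept their calls. The Mmp9 call was kept only without PBS replicates 2 or 3 or G-CSF replicate 5, that of Cd177 only without PBS replicates 2 or 3 or G-CSF replicates 2 or 3, and that of Csf3r only without PBS replicates 2 or 4 or G-CSF replicate 2. Otherwise their adjusted p reached 0.0792 and 0.0885 (both without PBS replicate 4) and 0.0886 (without PBS replicate 1).

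The list of B cell and precursor genes shifted downward (median -0.55) from low levels, with a median in PBS of 4.46. Of 17 measured, 3 fell (7 adjusted over the list alone), 0 rose and 14 did not pass. They were Cd79a, a chain of the B cell receptor complex (2.11-fold, from 4.46 ± 0.43 to 3.38 ± 0.25, adjusted p = 0.0227), Ms4a1, which encodes CD20 (1.62-fold, adjusted p = 0.0354), and Dntt, terminal transferase (1.63-fold, adjusted p = 0.0462). Camera gave an adjusted p of 2.83e-10 (0.0289 with an estimated correlation and 6.17e-09 with the set block), with a median of -0.48 in set 1 and -0.51 in set 2. Of 10 erythroid genes, Car1 and Rhag (-1.25, adjusted p = 0.0312) fell, 0 rose and 8 did not pass; adjusted over the list alone, 3 fell. The erythroid list passed camera downward (adjusted p = 1.77e-06; median -0.44, -0.20 without PBS replicate 1, -0.77 in set 1 and -0.13 in set 2), but not with an estimated correlation (adjusted p = 0.0657 with an estimated correlation). Of 18 macrophage and monocyte genes, 0 passed over all genes in limma (3 at an unadjusted p under 0.05) and 2 fell when adjusted over the list alone, and the list did not pass camera (median -0.07, adjusted p = 0.0573). It passed downward with the set block (0.0499) and in set 1 (median -0.18, adjusted p = 0.00185) but not in set 2 (median 0.07, adjusted p = 0.840). It also passed with the neutrophil covariate (median -0.43, adjusted p = 5.49e-05), with array weights (0.0123) and without PBS replicate 3 (0.0174), PBS replicate 4 (median -0.20, 0.0182) or G-CSF replicate 4 (median -0.18, 0.0198). It did not pass with only brighter probe sets (median 0.33, adjusted p = 0.346) or without PBS replicate 2 (median -0.03, adjusted p = 0.467), so a fall of these markers stayed open. C1qb, a complement chain, was at -0.77 (adjusted p = 0.0538) and passed with the set block (0.0183) and without PBS replicate 3 (0.0274). With 1 array left out, the Cd79a call was kept only without PBS replicate 3 or G-CSF replicate 5, those of Ms4a1 and Rhag only without PBS replicate 2, and that of Dntt only without PBS replicate 1. The highest adjusted p was 0.0748 for Cd79a (without PBS replicate 2), 0.102 for Ms4a1 (without PBS replicate 1), 0.101 for Rhag (without PBS replicate 4) and 0.149 for Dntt (without PBS replicate 2).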

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

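The arrays of each of 114 named genes, and 5 measures of each array (the quartiles and median of its values and its neutrophil and ribosomal list means), were checked for a single array far from the rest of its group with Dixon's criterion. The weighing of granulocyte RNA in the neutrophil list used tests chosen only after its rise had been seen. Chance alone flags about 1 in 20 groups, or 11.9 of the 238 tested here, and 11 were found. In PBS replicate 2, Stfa3 was at 4.79 (others 3.71 to 3.85), Serpinb1a at 5.92 (others 4.42 to 4.58) and Nkg7 at 7.35 (others 4.40 to 4.77). In PBS replicate 3, Slco1a4 was at 3.97 (others 5.17 to 5.39) and Fosl2 at 6.67 (others 7.30 to 7.36). Col1a1 was at 6.95 in PBS replicate 4 (others 6.72 to 6.74). Among G-CSF arrays, Wfdc17 was at 7.76 in replicate 2 (others 9.66 to 10.28). Fosl1 was at 6.11 in replicate 3 (others 6.79 to 7.04), where the platelet chemokine Ppbp was at 8.91 (others 3.85 to 4.44). In replicate 5, Rtp4 was at 7.45 (others 7.74 to 7.85) and Cd74 at 5.48 (others 5.01 to 5.12). When probe sets without a single gene symbol were tested together with the rest, 18 of 13764 passed the threshold in limma, 7 upward and 11 downward, and 759 had an unadjusted p under 0.05.

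The rise of the neutrophil list and the high PBS replicate 2 form a pattern that granulocyte RNA in the sorted cells could explain, although the lineage gate should remove such cells. Within groups, the list members varied together from array to array with a mean correlation of 0.486, as such RNA would give. This was above the highest value of random lists of that size (0.259). Lists of immediate early (0.539), megakaryocyte (0.536) and ribosomal genes (0.495) varied together as much, so the value does not single out granulocyte RNA. S100a8, which granulocytes express strongly, was at 11.66 in PBS and 12.51 in G-CSF, S100a9 was at 11.51 and 12.18, and 0 of the 20 members belong to another list. A difference between the array sets was argued against, since the list mean was higher in G-CSF by 0.719 in set 1 and by 1.14 in set 2. Whether CAR cells themselves raised any of these genes stayed open, and so did the G-CSF treatment as the reason for more granulocyte RNA.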

How the results depend on the processing

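The fits with the array sets, with G-CSF replicates 4 and 5 as 1 replicate and with the neutrophil covariate were chosen only after the data had been seen. The 353 called probe sets became 181 over all probe sets, 210 at 2-fold or more, 598 with the array set block, 202 in set 1, 59 in set 2, 49 with the neutrophil covariate, and 210 (without PBS replicate 1) to 318 (without PBS replicate 3) with 1 array left out. With the neutrophil covariate, the 353 changes kept a median of 101% of their size and all kept their direction, while the median SE grew 1.56-fold, because the covariate shares an r squared of 0.557 with the groups; Vcam1 went from -1.07 (SE 0.13) to -0.99 (SE 0.21) and lost its call. Apart from the replicate block given below, other settings gave 241 to 504 calls. The count of 241 came with G-CSF replicates 4 and 5, the most alike pair (SD of log2 difference 0.279, other pairs 0.372 or more), as 1 replicate. The 59 list members became 32 in set 1, 17 in set 2, 15 with the covariate and 30 (without G-CSF replicate 1) to 49 (without PBS replicate 3). Of the 17 lists, 9 passed with an estimated correlation and 13 with fry, and the 9 kept their calls in all 22 settings. With the replicate number as a replicate block, 180 probe sets and 36 members were called. The deviations of same-numbered arrays from their group means correlated with r of 0.28, 0.14, -0.28 and 0.35. All such r between a PBS and a G-CSF array were positive within an array set and negative across sets. They therefore cannot show whether the numbers paired the arrays. The following values changed sign, for genes and list medians that did not pass in the main analysis; the cause was not tested. Brighter probe sets gave 0.00115 for osteoblast, -0.0651 for chondrocyte, 0.330 for macrophage, -0.234 for mature osteoblast and -0.0890 for Schwann cell lists. Array weights gave -0.0304 for Hspa9, -0.122 for oxidative phosphorylation (then called, adjusted p = 0.0303), 0.0484 for stem and progenitor and -0.0822 for mature osteoblast lists. The replicate block gave -0.00381 for mature osteoblast and -0.00316 for Schwann cell lists, and the array set block -0.0419 for the latter. Set 1 gave 0.0522 for Clec1b, 0.0494 for Foxd3, -0.207 for oxidative phosphorylation (called, adjusted p = 0.00612), 0.0887 for megakaryocyte, 0.0770 for stem and progenitor and -0.0851 for mature osteoblast lists. Set 2 gave -0.00873 for Tnfsf13b, 0.135 for Sc5d, 0.181 for cholesterol synthesis, 0.0728 for macrophage, 0.0520 for endothelial, -0.0906 for mature osteoblast and -0.0123 for Schwann cell lists. The covariate gave -0.809 for Nkg7, -0.101 for Gfap, 0.0204 for osteoblast, 0.125 for cholesterol synthesis, -0.00672 for oxidative phosphorylation, -0.00597 for T and NK cell, 0.0327 for megakaryocyte and 0.0935 for stem and progenitor lists. With 1 array left out, values ran from -0.0348 to 0.239 for Hspa9, -0.00638 to 0.293 for Gfap, -0.0203 to 0.137 for chondrocyte, -0.132 to 0.0952 for cholesterol synthesis, -0.153 (without PBS replicate 3, called, adjusted p = 0.00697) to 0.141 for oxidative phosphorylation, -0.0305 to 0.131 for T and NK cell, -0.186 to 0.0349 for megakaryocyte, -0.170 to 0.0781 for stem and progenitor, -0.128 to 0.0889 for mature osteoblast and -0.106 to 0.0493 for Schwann cell lists. In 22 settings, calls were gained for macrophage genes in 7, megakaryocyte in 3, endothelial and T and NK cell in 2 each, and the restraining ligands, unfolded protein response and cholesterol synthesis in 1 each. RMA values carry no signal over background, so dim genes such as the B cell markers are the least certain.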

Other observations

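The tests chosen only after the result was seen were those of the array sets, of the spread among identity genes and of the TGF-beta response genes, and the splits with an estimated correlation were added after those with the preset correlation had been counted. Several lists of metabolism and growth, and that of the immediate early and dissociation response, moved upward with few members past the threshold in limma. All of these lists lost their calls with an estimated correlation. Of 24 glycolysis and hypoxia genes, 1 rose (5 adjusted over the list alone), namely Pfkfb3, an activator of glycolysis (0.75, adjusted p = 0.0485), with camera at adjusted p = 4.18e-07 (adjusted p = 0.0657 with an estimated correlation) and a median of 0.17 in set 1 and 0.48 in set 2. Adm, adrenomedullin, was at 1.34 (adjusted p = 0.0555) and Bnip3 at 0.65 (adjusted p = 0.0690), and both passed with the array set block (0.0464 and 0.0291), when 4 members of the list rose. Of 29 cell cycle genes, 1 rose (2 adjusted over the list alone), the mitotic kinesin Kif11 (0.67, adjusted p = 0.0287), with camera at 6.05e-04 (adjusted p = 0.211 with an estimated correlation). That call was lost in set 1 (median 0.12, adjusted p = 0.0683) but not in set 2 (median 0.45, adjusted p = 1.90e-05). Of 23 ribosomal protein genes, 0 passed in either count (4 at an unadjusted p under 0.05), with camera at 1.64e-06 (adjusted p = 0.261 with an estimated correlation). Their median change of 0.37 was 0.15 in set 1 and 0.55 in set 2, and became 0.65, 0.63 and 0.19 without PBS replicates 1, 2 and 3 and 0.56 without G-CSF replicate 4 or 5. Of 26 genes of the immediate early and dissociation response, 0 passed (4 at an unadjusted p under 0.05) and 1 rose adjusted over the list alone. For this list camera gave an adjusted p of 6.05e-04 (adjusted p = 0.457 with an estimated correlation). This call was also lost without G-CSF replicate 1 (adjusted p = 0.0622). The list median of 0.33 became 0.18 without that array and 0.55 without G-CSF replicate 3. The Pfkfb3 call was kept only without G-CSF replicate 2, and the Kif11 call was lost whichever array was left out, at adjusted p of up to 0.138 (without PBS replicate 1) and 0.0765 (without G-CSF replicate 5).

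The other lists did not pass camera. Of the unfolded protein response (25 genes, adjusted p = 0.112), cholesterol synthesis (16 genes, 0.734) and oxidative phosphorylation (30 genes, 0.933), 0 members passed in either count in limma, with 1, 0 and 0 at an unadjusted p under 0.05. The same held for markers of megakaryocytes (8 genes, 0.307), stem and progenitor cells (13 genes, 0.935) and Schwann cells (7 genes, 0.933), with 0, 1 and 0 at an unadjusted p under 0.05; the last 2 had a median and a test that differed in sign. Of 8 plasma cell genes (0.176) and 11 T and NK cell genes (0.209), 1 fell and 1 rose adjusted over the list alone, and 1 of each had an unadjusted p under 0.05. Of 19 endothelial genes (0.374), 2 rose and 2 fell adjusted over the list alone (4 at an unadjusted p under 0.05), and Emcn was at 0.70 (adjusted p = 0.0690, and 0.0471 with the array set block).

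Other splits of the 9 arrays into groups of 4 and 5 were fitted, 100 in all with the real one. As many as 353 probe sets were called in 2 of them, the real split and the split that follows the array sets, which called 1738; the highest of the rest was 63. The count was thus rare among the splits, which argues against chance as its reason but does not exclude it. Most other splits mixed treated and untreated arrays, which puts the treatment difference into their spread and lowers their counts. The larger split points to a structure of the arrays, with which as a block 598 were called. A hidden structure that lines up with treatment cannot be told apart from treatment by such splits. The 59 list members that passed were reached by 1 split, the real one (highest other 53). For the lists, 10 of 100 splits shifted at least 17 with the preset correlation (highest other 21), so chance could not be excluded. Besides the real one, these splits had 3 or 0 PBS arrays in the group of 4 and so kept part of the treatment contrast. How often chance alone shifts 17 lists can therefore not be read from them. With an estimated correlation only 1 split, the real one, reached 9 (highest other 1).

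The set of changed probe sets could reflect the array sets or granulocyte RNA. The array sets are argued against as the whole reason, since each holds both groups in near-equal shares (2 and 2 PBS arrays, 3 and 2 G-CSF arrays). With the set as a block, 100% of the 353 were still called and each kept at least 93.8% of its change. That balance and the selection of the 353 largely fix these percentages, so they add little. Granulocyte RNA of the same make-up in both groups is argued against too, but only weakly and only as the main reason for the median changed probe set. The slope on the neutrophil list mean within groups accounted for a median of -0.274% of the rise (-2.97% to 2.06% with 1 array left out) and -0.897% of the fall (-2.39% to 15.3%). It gave more than 50% for 6 of 159 risen (neutrophil list members left out) and 1 of 191 fallen probe sets. Stfa2 was at 40.4% and Stfa3 at 26.8%, under 50% although both are abundant in granulocytes, and Serpinb1a was at 44.6%. The 50% cut thus missed genes of granulocytes, and the count of 6 may be too low. The genes named here and those over 50% stayed open. The slope cannot see genes that granulocytes themselves raised with G-CSF. Even the list member Csf3r was still at 0.59, against 0.94, with the list mean as a covariate, so a low share clears no single gene. An effect of G-CSF on CAR cells remains as a hypothesis, and a shift within the sorted population was not excluded.

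The fall of the identity list could come from a lower share of CAR cells in the sort. A lower share alone would lower abundant members alike, if other sorted cells express them little, which was not tested. The changes of 24 members with a PBS level of at least 10 ran from -2.56 to 0.24. Their SD was 0.693, or 4.96 times their median SE of 0.140. This spread argues against a lower share as the sole reason, but cannot exclude a lower share together with other changes. The array sets are argued against, as the mean of all 33 members changed by -0.664 in set 1 and by -0.484 in set 2. A change of expression within the cells may therefore be considered, as may a shift between kinds of CAR cells, which was not tested.

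Since Bmp4 fell 6.06-fold, BMP signalling in the cells could be lower. A list of 13 measured BMP target genes gave a camera p of 0.254 and a median of -0.04 with 0 members past the threshold. Members lay in both directions, with Id1 at -0.66 (adjusted p = 0.0618) and Nog at 0.77 (adjusted p = 0.274). At an unadjusted p under 0.05 in limma, 4 members were lower and 1 was higher. The test had been set to count against the idea at such a p, but a p over the threshold bounds no shift, so the question stayed open, the more so as the BMP antagonist Chrdl1 also fell.

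The rises of collagens and Acta2 may belong to a TGF-beta response. Acta2 is also a marker of smooth muscle cells and pericytes, whose share in the sort was not tested. A list of 18 measured response genes left out collagens, Acta2 and Tagln, and 1 further gene whose change had been seen. It was higher in G-CSF with a camera p of 0.00507 (adjusted p = 0.0101, together with the BMP list). With an estimated correlation the p was 0.0474, and 0.0949 when adjusted, which did not pass; with the array set as a block it was 7.60e-04. Only Itgb5, an integrin chain, rose past the threshold (1.18, adjusted p = 0.00548), and members such as Thbs1 (-0.51) and Snai2 (-0.44) lay the other way, so the response remains a hypothesis.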
